A study of Ovis aries with 16 samples.

How the data were processed

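The data are RNA-seq libraries of amnion, the avascular inner fetal membrane, from 16 pregnant sheep with singleton fetuses, in 4 groups of 4 animals. Per the labels, polyadenylated RNA was selected from total RNA, fragmented, copied from random hexamers, ligated to indexed adaptors, amplified by PCR and sequenced on an Illumina HiSeq instrument. The deposited values are counts of reads per gene. Per the submitters' processing notes, FastQC 0.11.3 and HTSeq 0.6.1 were used, together with DESeq2. The aligner, the genome build, the gene annotation and the strand setting are not given in the sources used here. Without a strand setting, reads of overlapping genes and of a gene and its antisense partner cannot be told apart, and values of near-identical genes are uncertain.

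The table held 25197 Ensembl sheep gene IDs in 18 columns, each naming a library and a lane of the sequencer. All 18 columns matched a sample by name. The values were whole numbers that summed to a different total in each column, and 4551 IDs were at 0 in every column. UDR 2 and UDR 3 had been sequenced in lanes 2 and 3. In UDR 2, the chi-square statistic of the 2 runs over 13637 genes was 1.032 per degree of freedom, and 0 genes differed at an adjusted p under 0.05. In UDR 3 it was 1.059 over 14018 genes, and 2 genes differed. Between different libraries the smallest such statistic was 39.61. The runs of a library were therefore summed and counted as 1 sample. The control libraries and UD 1 and 2 were in lane 1, UD 3 and 4 and the UDR libraries in lane 2, and the IA libraries in lane 3, with the second runs of UDR 2 and UDR 3. IA and the controls therefore shared no lane, but UD links lanes 1 and 2 and UDR links lanes 2 and 3.

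Genes were kept where edgeR's filterByExpr found enough counts for the groups. This left 14148 genes, which held 99.91% of all counts. Counts were scaled with TMM factors and tested with edgeR 4.0.16 in R 4.3.3, with the quasi-likelihood F test, robust estimation and all 16 libraries in 1 fit. Group was the only term. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05, and every test was two-sided. In all, 5 comparisons and 1 test of any difference among the groups were fixed before the data were examined; the comparison of IA with UDR was added afterwards. Log2 CPM used a prior count of 2. Intervals of shares are exact binomial intervals at 95% and cover counting error only, since PCR copies are not independent molecules.

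The separation of groups was measured as the share of the variance in log2 CPM, over all genes tested, that lay between groups. It was tested by exact permutation for pairs of groups and by 100000 permutations for the 4 groups. Clusters of co-varying genes were made without the group labels, by average linkage on 1 minus the correlation over the 3000 most variable genes. The tree was split at 8 clusters, and the 4 with at least 50 genes were kept. These measures were chosen after the data were examined.

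The gene IDs could not be given names. The reference gene table used here, of the assembly ARS-UI_Ramb_v3.0, lists 35057 genes, and 0 of the 25197 IDs matched it. The files do not pair IDs with names either. Before the data were examined, 40 lists of gene symbols had been fixed, 12 of them for vesicular transport and others for cell types, along with a rule for naming genes. With 0 of their symbols found, neither the lists nor the rule could be applied. In their place, the 2 higher and 2 lower genes with the smallest p in any comparison with the controls are given by ID.

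Each test was first tested on simulated counts with the means, library sizes and gene-wise dispersions of the 14148 genes, in which 200 genes were changed, 50 for each of 4 fold sizes. In the simulated comparison of UD with C, edgeR recovered 2% of genes changed 2-fold, 52% at 4-fold, 64% at 8-fold and 92% at 16-fold, with 2 false calls. DESeq2 recovered 20%, 76%, 82% and 98%, with 48 false calls. Limma-voom with sample quality weights recovered 6%, 52%, 66% and 88%, with 0 false calls. For UDR and IA with C the false calls were 2 and 5 by edgeR and 56 and 42 by DESeq2. They were 3 and 6 by limma-voom with sample quality weights. With 200 genes changed, DESeq2 made more false calls in each comparison than the threshold on its adjusted p allows. A call by DESeq2 alone is therefore weak support. The simulated genes varied independently of each other, unlike real ones, and no simulated library stood apart over many genes. The simulation therefore cannot judge calls that rest on such libraries.

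The alternatives were RLE and upper quartile scaling, no filter beyond 1 count, a filter of CPM above 1 in 4 libraries, DESeq2 1.42.0, limma-voom with sample quality weights (limma 3.58.1), the replicate number as a block, fits of only the groups compared, and each library left out in turn. Added after the data were examined were first runs only, a lane term for C, UD and UDR, a lane term over all 16 libraries with the lane 3 runs of UDR 2 and UDR 3, fits within a lane, fits without IA 2 and UDR 3, limma-voom without weights, and surrogate variables from sva 3.50.0. The proteins and fetal fluids named in the design of the study were not analysed here.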

Results

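Transcripts were measured in the amnion of fetal sheep whose amniotic fluid balance had been altered for 2 days. Part of the amniotic fluid leaves the sac across the amnion into fetal blood, a route called intramembranous transport, and the study asked how transcripts of vesicular transport respond when its rate is changed. The 16 animals entered the study at 121 ± 0.5 days of gestation (SE), with term at 145 to 150 days. The controls (C) had no change of fluid. In the UD group fetal urine was drained and not replaced. In the UDR group it was drained and an equal volume of lactated Ringer's solution, a salt solution, was given. In the IA group lactated Ringer's solution was infused into the amniotic sac at 2 liters per day. Each group held 4 animals, and 1 library was made from each.

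The libraries held 12245460 to 30767263 counts. The highest totals were those of UDR 2 and UDR 3, with 30767263 and 25646747 counts, the only libraries with 2 runs. A mean of 16615.2 ± 300.3 genes (SD, n = 4) had counts in C, 16810.8 ± 382.9 in UD, 16884.8 ± 499.8 in UDR and 16644 ± 377.8 in IA. The 10 most abundant genes took 8.46% ± 0.889 of the counts in C, 15.99% ± 4.45 in UD, 9.93% ± 1.94 in UDR and 13.6% ± 6.11 in IA (SD, n = 4). The common biological coefficient of variation was 0.579. The median SD of log2 CPM within a group was 0.42 in C, 0.56 in UD, 0.59 in UDR and 0.48 in IA.

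The 16 libraries differed along a few strong axes that crossed the groups. The first principal component took 35.1% of the variance, the second 21.4% and the third 12.1%. On the first, IA 2 scored 172, UD 1 113.1 and UD 4 59.7, while UDR 3 scored 27.7 and no other library more than 6.45. On the second, UDR 3 scored 110.8, UDR 2 88.6, UD 2 80.6 and C 1 42.1. The 4 groups accounted for 21.1% of the variance of the first component and for 24.8% of the second, with permutation p of 0.395 and 0.285 (adjusted p = 0.527 for both, over 4 components). Over all genes they accounted for 21.1% of the variance, where chance gives 20%, with a permutation p of 0.363.

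**Figure D1:**
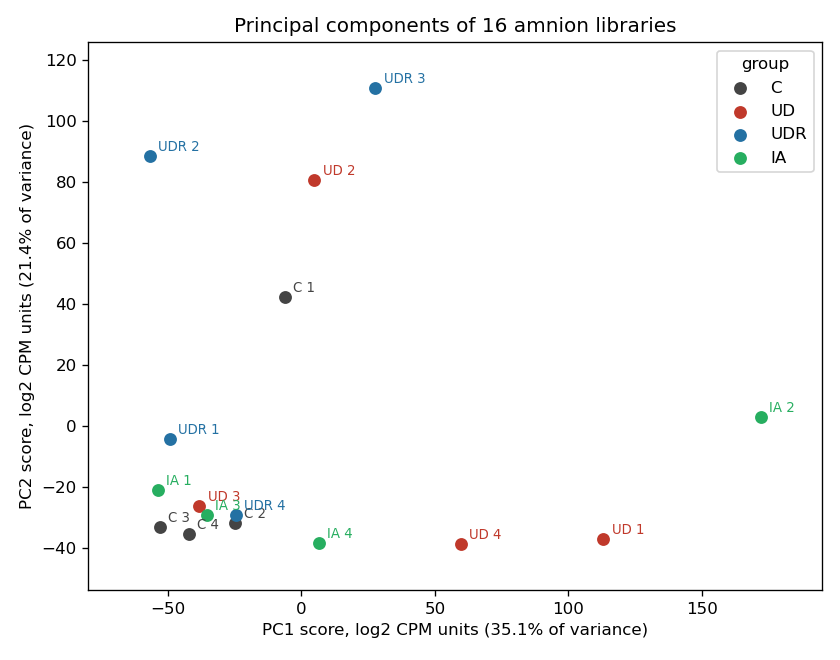
Scores of the 16 libraries on the first 2 principal components of log2 CPM (x axis, 35.1% of the variance; y axis, 21.4%), each point a library coloured by group. IA 2, UD 1 and UD 4 lie at the right, with scores of 172, 113.1 and 59.7, and the libraries of each group are spread among those of the others.

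Genes that varied together fell into 4 clusters. Cluster 1, of 1543 genes, was high in 2 of the 4 UD libraries and in IA 2. Its mean log2 CPM lay 2.80 above the mean of C in UD 1, 1.98 in UD 4, 2.90 in IA 2 and 1.11 in IA 4, against 0.05 in UD 2 and 0.15 in UD 3. Cluster 2, of 709 genes, differed from C by -4.55 in IA 2, by -1.59 in UDR 3, by -1.26 in UD 2 and by -1.21 in UD 1. Cluster 3, of 620 genes, was high in a library of C and of UD and in 2 of UDR, by 1.54 in C 1, 1.92 in UD 2, 1.99 in UDR 2 and 2.39 in UDR 3. Cluster 4 held 93 genes. The groups accounted for 28.7% of the variance of cluster 1, 9.65% of cluster 2, 15.9% of cluster 3 and 3.43% of cluster 4, where chance gives 20%. Permutation p-values adjusted over the 4 clusters were 0.92 for cluster 1 and 0.93 for the others.

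**Figure D2:**
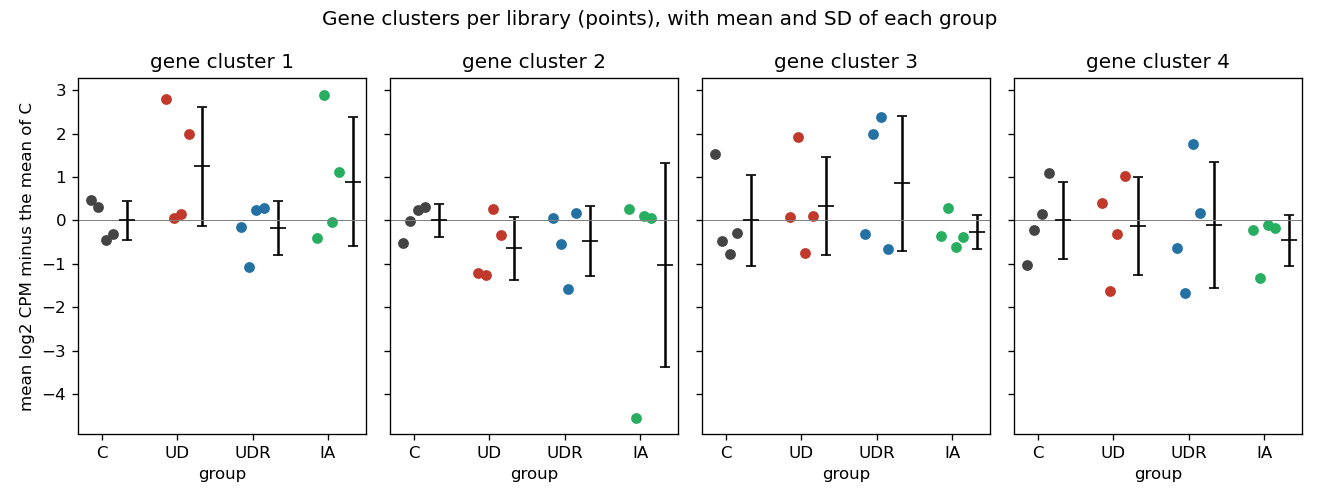
Mean log2 CPM of the genes of each of 4 clusters, relative to the mean of the C libraries (y axis), by group (x axis); points are libraries, and the bar beside them gives the mean and SD of the 4. In cluster 1 the UD libraries span 0.05 to 2.80 and the IA libraries -0.41 to 2.90, and in cluster 2 IA 2 lies at -4.55.

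The comparison of UD with C asks what draining fetal urine without replacement does to amnion transcripts. The amnion of drained animals was uneven: cluster 1 lay 1.24 above C on average in log2 CPM (SD 1.36 in UD and 0.45 in C, n = 4; exact permutation p = 0.171, adjusted p = 0.96 over 24 tests), with UD 1 at 2.80 and UD 4 at 1.98. Without UD 1 the difference was 0.73. No single gene passed the main test. edgeR called 0 of 14148 genes, with a smallest adjusted p of 0.89, while 773 had an unadjusted p under 0.05, against 707 expected by chance. Of these, 660 were higher and 113 lower in UD. The number was 1277 with a lane term for C, UD and UDR, and 1748 within lane 1, where UD 1 and UD 2 were sequenced with the controls, again with 0 genes called. Both fits set only UD 1 and UD 2 against C. In the first, UD 3 and UD 4 served only to estimate the lane. The higher numbers are therefore not a lane correction of the comparison of 4 UD animals. DESeq2 called 14 genes, and limma-voom with sample quality weights called 3320, a number that was 0 without UD 1 or without UD 4, 4852 without UD 2 and 3837 without UD 3. In 269 genes every UD library lay above every C library and in 141 below, together 2.90% of genes, where chance gives 2.86%. Among genes lower in UD the smallest p was that of ENSOARG00000016781. It was at 0.445 ± 0.113 CPM in UD and 3.46 ± 3.08 in C (SD, n = 4). Its log2 fold change was -2.94 (SE 0.70), with an adjusted p of 0.89 by edgeR. DESeq2 called it, and so did limma-voom with sample quality weights, with a log2 fold change of -3.46. Limma-voom without weights gave -2.21 and did not call it. The libraries C 1 and C 4 held it at 0.734 and 0.856 CPM. On simulated counts of UD with C, DESeq2 made 48 false calls, so its call is weak support. Groups accounted for 20.6% of the variance between the 8 libraries, where chance gives 14.3% (exact permutation p = 0.171, smallest possible 0.0286, adjusted p = 0.548 over 6 comparisons). With 1 of the 8 libraries left out the share was 16.8% (without UD 1) to 31.8% (without UD 3; exact permutation p = 0.0571). With fewer libraries chance gives a higher share than 14.3%, so these shares cannot be set against it.

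The comparison of UDR with C asks what drainage does when the fluid volume is kept. Cluster 3 lay 0.85 above C in mean log2 CPM (SD 1.56 in UDR and 1.05 in C, n = 4; exact permutation p = 0.286, adjusted p = 0.96), with UDR 2 and UDR 3 high and UDR 1 and UDR 4 at -0.32 and -0.65. It was 0.34 without UDR 3, 0.48 without UDR 2, 1.37 without C 1 and 1.35 without UDR 4. ENSOARG00000007806 was at 47.2 ± 48.9 CPM in UDR and 6.25 ± 1.38 in C (SD, n = 4), a log2 fold change of 2.92 (SE 0.53). Its 4 UDR values, from 16.1 to 120.2 CPM, lay above its highest C value of 8.08, and the highest was that of UDR 3. ENSOARG00000013082 was at 130.4 ± 147.6 CPM against 12.2 ± 3.58, a log2 fold change of 3.41 (SE 0.72), again with its highest value, 346.2 CPM, in UDR 3. Without UDR 3 the log2 fold changes were 1.87 and 2.26. They were 2.41 and 3.02 with a lane term for C, UD and UDR. With the lane as a term over all 16 libraries they were 1.25 and 1.16. In that fit UDR 2 and UDR 3, the highest UDR libraries for both genes, do not enter the comparison with C, so these lower values are not a lane correction of the 4 UDR animals. Each had an adjusted p of 0.685 by edgeR, so neither passed. Both were called by DESeq2, which made 56 false calls on simulated counts of UDR with C, so this is weak support. edgeR called 0 genes, and 863 had an unadjusted p under 0.05, 598 of them higher and 265 lower in UDR. The number was 514 with a lane term for C, UD and UDR and 128 with one over all 16 libraries. The first term rests on UD 1 and UD 2 against UD 3 and UD 4. The second also rests on UDR 1 and UDR 4 against UDR 2 and UDR 3. Both therefore take up differences between animals as well, and with the second UDR 2 and UDR 3 do not enter the comparison with C. DESeq2 called 31 genes and limma-voom with sample quality weights 0. The groups did not overlap in 2.87% of genes, where chance gives 2.86%, and accounted for 16.6% of the variance (exact permutation p = 0.2, adjusted p = 0.548).

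The comparison of IA with C asks what added amniotic volume does. Cluster 1 lay 0.89 above C in mean log2 CPM (SD 1.49 in IA and 0.45 in C, n = 4; exact permutation p = 0.343) and cluster 2 differed by -1.03 (SD 2.35 and 0.37, n = 4; exact permutation p = 0.686); the adjusted p was 0.96 and 0.984. Both rested on IA 2: without it the difference was 0.23 in cluster 1 and 0.15 in cluster 2, where the other 3 IA libraries lay above the mean of C. ENSOARG00000001244 was at 4.91 ± 2.44 CPM in IA and 25.2 ± 15.5 in C (SD, n = 4), a log2 fold change of -2.36 (SE 0.51), with an adjusted p of 1 by edgeR and a call by DESeq2. Its IA values of 2.10 to 8.05 CPM lay below its lowest C value of 15.2. On simulated counts of IA with C, DESeq2 made 42 false calls, so its call is weak support. edgeR called 0 genes, and 623 had an unadjusted p under 0.05, 527 of them higher and 96 lower in IA. DESeq2 called 5 genes and limma-voom with sample quality weights 0. The groups did not overlap in 1.86% of genes, where chance gives 2.86%. They accounted for 13.9% of the variance (exact permutation p = 0.457, adjusted p = 0.548), or 21.6% without IA 1 (exact permutation p = 0.2). Chance gives a higher share of the variance when a library is left out. IA and C shared no lane. With the lane as a term over all 16 libraries, edgeR called 0 genes and 414 had an unadjusted p under 0.05. This fit held only the lane 3 runs of UDR 2 and UDR 3. It therefore links lanes 1 and 2 through different UD animals and lanes 2 and 3 through different UDR animals.

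The comparison of UDR with UD asks what replacing the drained fluid changes. Cluster 1 differed by -1.42 in mean log2 CPM, at -0.17 in UDR and 1.24 in UD (SD 0.63 and 1.36, n = 4; exact permutation p = 0.171, adjusted p = 0.96), and by -0.90 without UD 1. edgeR called 0 genes, with a smallest adjusted p of 0.471. An unadjusted p under 0.05 was found for 1256 genes, of which 368 were higher and 888 lower in UDR. DESeq2 called 155 genes, 11 higher and 144 lower, and limma-voom with sample quality weights called 1516, a number that was 0 without UD 1 or without UD 4, 3779 without UD 2 and 3082 without UD 3. Groups accounted for 17.7% of the variance (exact permutation p = 0.286, adjusted p = 0.548). With the lane in the model of C, UD and UDR, 530 genes had an unadjusted p under 0.05 and 0 were called by edgeR. With the lane as a term over all 16 libraries the number was 99, again with 0 called. With the first lane term UDR was set against UD 3 and UD 4 alone, and with the second only UDR 1 and UDR 4 were. Both lane terms thus take up differences between animals of a group.

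IA and UD are the extremes of added and removed volume. The difference between them was smaller than in most regroupings of the 8 libraries: groups accounted for 7.19% of the variance, where chance gives 14.3% (exact permutation p = 0.943). edgeR called 0 genes and 116 had an unadjusted p under 0.05, 28 higher and 88 lower in IA. DESeq2 called 3 genes, and limma-voom with sample quality weights 1403, a count that was 0 without UD 1 or without UD 4, 3459 without UD 2 and 2569 without UD 3. IA and UD shared no lane; the number at an unadjusted p under 0.05 was 693 with the lane as a term over all 16 libraries and 653 with surrogate variables. Between IA and UDR, a comparison added after the data were examined, edgeR called 0 genes and 1283 had an unadjusted p under 0.05, 739 higher and 544 lower in IA. DESeq2 called 53 and limma-voom with sample quality weights 0. Groups accounted for 15.5% of the variance (exact permutation p = 0.429, adjusted p = 0.548). In the edgeR test of any difference among the 4 groups, 0 genes passed, the smallest adjusted p was 0.523 and 909 genes had an unadjusted p under 0.05. DESeq2 called 137 and limma-voom with sample quality weights 3822. With the lane as a term over all 16 libraries, edgeR called 1 gene between IA and UD and 9 between IA and UDR. For any difference it called 3. In that fit 2093 genes between IA and UDR and 1369 for any difference had an unadjusted p under 0.05. In that fit IA with UDR set IA against UDR 2 and UDR 3 alone, and UDR 1 and UDR 4 served only to estimate the lane. IA with UD joined that difference to the one of UDR 1 and UDR 4 against UD 3 and UD 4. The lane term thus takes up differences between animals of a group.

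The precision of these comparisons was set mainly by the spread between libraries and little by counting error. In the negative binomial model, counting error made up a median of 1.67% of the squared coefficient of variation of a gene. With 1 library per animal, differences between animals and those of sampling or library preparation cannot be told apart. The median SE of a log2 fold change against C was 0.41, and the median 95% interval reached 0.88 to either side, or 1.84-fold. The interval stayed within 2-fold of no change for 40.5% of genes in UD, 36.4% in UDR and 41.6% in IA. On simulated counts edgeR recovered 52% of genes changed 4-fold in UD, 56% in UDR and 54% in IA, and 2%, 6% and 14% of those changed 2-fold, so a 2-fold change of a typical gene was rarely detectable with 4 animals per group.

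**Figure D3:**
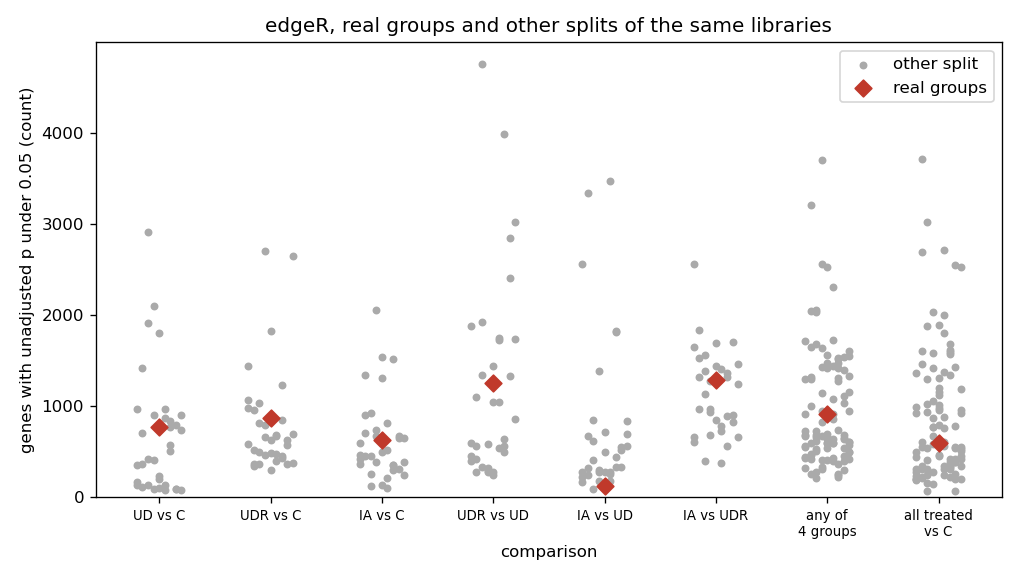
Number of genes with an unadjusted p under 0.05 by edgeR (y axis) for each comparison (x axis); red diamonds are the real groups, grey points other splits of the same libraries into groups of the same sizes. The real counts, from 116 to 1283, lie inside the range of the other splits, which reach 2907 for UD with C, 2703 for UDR with C and 2058 for IA with C.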

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

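Tests of the sequencing run, of a response shared by the UDR animals, of another tissue, of the lane, of the treatment group, of the quality weights, of single UD libraries and of a change in all 4 UD animals were chosen after the results were seen, as were the measures below. Of 44 groups of 4 libraries examined for a value far from the other 3, 5 held one, where chance gives about 2.2; the measures are not independent of each other. IA 2 had a median Spearman correlation of 0.77 with the other libraries, against 0.946 to 0.957 in the rest of its group. IA 2 also stood apart in cluster 2, at -4.55, and in cluster 4, at -1.33 in log2 CPM relative to C. C 1 stood apart from its group on the second principal component, at 42.1, and so did UD 2, at 80.6. UDR 3 stood apart in the share of counts of a set of 30 genes, at 4.87%, but those genes were chosen by their level in UDR 3, so this is not among the 5.

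The set of UDR 3 held the 30 genes that were above 10 CPM there and over 20 times above every other library. It took 4.87% of its counts (95% exact interval 4.87 to 4.88), against 0.0442% in IA 2, the next highest. A sequencing run is argued against, because the share in lane 2 over that in lane 3 was 0.998. For these 30 genes, a response to fluid replacement shared by the UDR animals is argued against, within what their choice allowed. UDR 1, 2 and 4 held 0.0101%, 0.0177% and 0.0148%, where the choice of the genes allowed up to 0.244%. Of the 12 libraries without replacement, 4 lay above UDR 1, 2 and 4 (IA 2, UD 2, UD 4 and IA 3, at 0.0442%, 0.0338%, 0.0294% and 0.0244%). Genes raised alike in all UDR animals could not enter the set, so a shared response in other genes is not covered. RNA of another tissue or cell type in UDR 3 stays open, because 0 of the listed marker genes could be found among the IDs; a response of this 1 animal was not tested.

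On the first principal component IA 2, UD 1 and UD 4 stood apart. The 100 most abundant genes held 1.91% of its squared loadings and 1.37% of the total variance, so they were not its main carriers. The scores without them correlated with the first ones at 0.99996. Leaving out so small a share of the variance could hardly have changed the scores, so this correlation adds no evidence. The 1543 genes of cluster 1, taken from the same values, were high in the same 3 libraries. The sequencing lane is argued against, as lanes held 4.88% of the variance of the scores and the 3 libraries came from 3 lanes. The treatment group held 21.1% of that variance, near the 20% that chance gives (permutation p = 0.395). This shows no part of it in the treatment, but leaves a small one open. The state or the cell makeup of the sampled membrane may differ between animals, but with no gene names this was not tested.

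Limma-voom with sample quality weights called 3320 genes between UD and C, and edgeR 0. The sample quality weights may be one cause, since limma-voom without weights called 0 genes. The count also rested on single UD libraries: it was 0 without UD 1 and 0 without UD 4, but 4852 without UD 2 and 3837 without UD 3. The weights were 5 for UD 4 and 1.12 for UD 1, against 0.375 for UD 2 and 0.354 for UD 3. The median called gene higher in UD lay 2.21 above the mean of C in log2 CPM in UD 1 and 1.77 in UD 4. It lay 0.552 above in UD 2 and 0.235 in UD 3, against 0.432 in C 1. These genes were picked by a fit in which UD 4 and UD 1 weighed most, but a shift of that size was not shared by UD 2 and UD 3. Whether a smaller change shared by all 4 UD animals adds to the count cannot be told apart. UD and C did not overlap in 2.898% of genes, where chance gives 2.857%, while another of the 35 splits reached 16.8%.

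Other splits of the same libraries gave as many genes, so chance cannot be excluded for any count below. For edgeR at an unadjusted p under 0.05, the splits with at least the real count were 13 of 35 for UD with C (773 genes, highest other 2907), 10 of 35 for UDR with C (863, 2703), 15 of 35 for IA with C (623, 2058), 14 of 35 for UDR with UD (1256, 4760), 33 of 35 for IA with UD (116, 3473) and 15 of 35 for IA with UDR (1283, 2565). They were 43 of 100 for any difference (909, 3704) and 50 of 100 for all treated animals against C (591, 3712). For genes called by DESeq2 they were 11 of 35 for UD with C (14 genes, highest other 924), 8 of 35 for UDR with C (31, 1054), 11 of 35 for IA with C (5, 844), 11 of 35 for UDR with UD (155, 3480), 24 of 35 for IA with UD (3, 1873), 18 of 35 for IA with UDR (53, 901) and 11 of 30 for any difference (137, 2916). For limma-voom with sample quality weights they were 5 of 35 for UD with C (3320, 5184), 14 of 35 for UDR with UD (1516, 6526), 7 of 35 for IA with UD (1403, 4447) and 6 of 100 for any difference (3822, 5735). Splits that called several times the real count point to a structure of the libraries that crosses the groups. For DESeq2 and UDR with UD, the split with 3480 genes set UD 2, UD 3, UDR 1 and UDR 2 against the rest, which does not follow the lanes.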

How the results depend on the processing

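First runs, lane terms, fits within a lane, fits without IA 2 and UDR 3, surrogate variables and limma-voom without weights were chosen after the data were examined, and the rest before. edgeR called 0 genes in every comparison with other scalings, other filters, only the groups compared, first runs and each library left out, where the lowest and highest count was 0. The cause of the following differences was not tested except for the weights. DESeq2 called 14 genes for UD with C, 31 for UDR with C, 5 for IA with C, 155 for UDR with UD, 3 for IA with UD, 53 for IA with UDR and 137 for any difference. Limma-voom with sample quality weights called 3320 for UD with C, 1516 for UDR with UD, 1403 for IA with UD and 3822 for any difference, and 0 for the other 3; without weights it called 0 in each. With surrogate variables 1 gene was called for UD with C and 1 for IA with C. Within lane 3, which held only UDR 2 and UDR 3 of their group, 1 gene was called for IA with UDR. A lane term for C, UD and UDR left 0 calls in their 3 pairs. With the lane as a term over all 16 libraries edgeR called 0 genes in these and in IA with C, 1 for IA with UD, 9 for IA with UDR and 3 for any difference. Lanes 2 and 3 are there told apart by different UDR animals, so the term takes up differences between them. The 2 runs of UDR 2 differed in 0 genes and those of UDR 3 in 2, with a chi-square per degree of freedom of 1.032 and 1.059. This argues against a large part of lanes 2 and 3 themselves in that term. Without IA 2 and UDR 3 all counts were 0.

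Leaving out 1 library moved the number of genes with an unadjusted p under 0.05. For UD with C it was 271 without UD 1, 401 without C 3 and 1393 without UD 3. For UDR with C it was 538 without UDR 3, 560 without C 2, 1370 without C 1 and 1548 without UDR 4. For IA with C it was 157 without IA 2, 278 without C 3, 348 without C 4 and 1000 without IA 1. For UDR with UD it was 499 without UD 1, 747 without UD 4 and 2443 without UD 3. For IA with UD it was 344 without UD 3 and 655 without IA 2, and for IA with UDR 855 without IA 2. Without both IA 2 and UDR 3 it was 1354 for UD with C, 223 for IA with C, 868 for IA with UD and 436 for IA with UDR. With surrogate variables it was 1594 for UDR with C, 790 for UDR with UD and 509 for IA with UDR. With no filter it was 1166 for UD with C, 969 for IA with C, 265 for IA with UD and 1390 for any difference, over more genes tested.

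The replicate numbers name different animals. Over 24 pairs of libraries with the same number the mean correlation of deviations was 0.0362 (-0.561 to 0.637). It was -0.00658 for pairs from different groups with different numbers. Among libraries of other groups, 8 of 16 libraries correlated best with their own number. What chance gives for that count was not computed, so some structure by number stays open. With the replicate number as a block edgeR called 0 genes in every comparison, and 645, 755 and 307 genes had an unadjusted p under 0.05 for UD, UDR and IA with C. Of 264 alternative values of cluster means 9 changed sign, none of which had passed. Of 120 alternatives for the 4 genes given by ID, 5 brought an adjusted p under the threshold, and the direction held in all. The planned counts of changed vesicular transport genes and the gene list tests were not run, because no ID could be given a symbol. Depth limits little for most genes: in the negative binomial model counting error made up a median of 1.67% of the squared coefficient of variation, and over 50% in 0 genes.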

Other observations

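The test of the spread of the controls and the comparison of all treated animals were chosen after the results were seen. The gene of cluster 1 with the most counts in IA 2 took 5.94% of the counts there, 5.52% in UD 1, 4.62% in UD 4, 2.14% in IA 4, 1.27% in UD 3 and 1.16% in UD 2, against 0.0992% to 0.788% in the 4 C libraries. It took 0.39% in IA 1, 0.342% in IA 3 and 0.0705% to 0.731% in UDR. The most abundant gene of the set found in UDR 3 reached 13100 CPM there, 319 CPM in IA 2, 165 CPM in UD 4, 59.4 CPM in UD 2 and 57.8 CPM in UD 1. It was at 22.1, 12 and 3.44 CPM in UDR 2, UDR 1 and UDR 4, and all 12 treated libraries, the lowest at 3.43 CPM, lay above the highest C library, at 2 CPM. Both genes were chosen after their values were seen. IA 2 also held 132 genes at levels over 20 times below every other library, while UDR 3 held 2.

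ENSOARG00000001244 was lower in all 12 treated libraries, at 2.10 to 12.3 CPM, than in all 4 C libraries, at 15.2 to 48.3 CPM. For the mean of the 3 treated groups against C, edgeR gave a log2 fold change of -1.80 with an adjusted p of 0.98, called 0 genes, and found 591 with an unadjusted p under 0.05. Over all genes tested, 12 lay higher and 4 lower in every treated library than in every C library, 16 in all, where chance gives 15.5.

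The C libraries lay closer together than those of the treated groups. The mean distance between 2 libraries, as a root mean square log2 difference per gene, was 0.949 in C, 1.27 in UD, 1.39 in UDR, 1.37 in IA and 1.25 between groups. A narrower spread in untreated animals is a hypothesis for this: 171 of the 1820 sets of 4 libraries were as close together as C, a share of 0.094, so chance stays open. The mean distance in IA includes IA 2, whose median Spearman correlation with the other libraries was 0.77. This correlation was 0.946 to 0.957 in the rest of IA and 0.9185 to 0.9525 in C. A mean distance without IA 2 was not computed, so the order of C and IA may rest on that library. All C libraries were in lane 1.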
